A study of Mus musculus with 4 samples.

How the data were processed

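RNA from naive CD4+ T cells of mouse spleen, cultured with IL-2 and TGF-beta with or without butyrate and taken at day 2, was hybridised to 4 Affymetrix whole-transcript gene arrays, 2 for control and 2 for butyrate cultures. Groups were taken from the agent named for each sample. The treatment protocol in the labels gives 0.1 mM butyrate for all 4 samples, so the concentration was read as that of the butyrate cultures. Each array holds 34760 probes, and the columns of all 4 were used, with 0 further columns of samples. The number of arrays limits the precision, among other limits given below. No genome build is given in the sources used here, so no coordinates were printed.

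The deposited log2 values were made by RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes, which give no version; the program and annotation are not given in the sources used here. The deposited numbers were not plain log2 intensities. They ranged from -4.44 to 3.84, and on each array between 59.3% and 61.8% of probes shared their value with other probes of that array, in ties of up to 112 probes. Tied probes lay below their level on other arrays by the size of the tie. The values were therefore read as log2 of the RMA log2 intensity divided by the number of probes that share it on that array. The intensity was recovered as 2 to the power of the deposited value times that number. After this step every array ran from 3.72 to 14.34, and Pearson's r across probes between arrays went from between 0.859 and 0.866 to between 0.986 and 0.992. Of 54662 untied values 0 lay under 0.55 of the median of the other arrays, and the lowest was at 0.626. A tie whose members all came out at least 1.2 times above their other arrays, or above the highest possible level, was taken for a coincidence of values. In such ties of 2 each value was read as untied, which was done for 156 values. In all 64 values stayed unsolved and 12 were missing, and the 76 probes concerned were left out, so that 34684 were kept. That the recovered intensity is on a log2 scale rests on its range and on the scale RMA writes, and no source states it. The test planned before the data were examined assumed plain log2 values; the recovery, the 1.2 limit and the intensity of 12 above which arrays were compared for order were chosen after seeing the data. No 2 arrays held identical values (0 pairs).

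Probes were named from the platform annotation supplied with the data. Of the probes 21640 had 1 gene symbol, 1321 several and 11799 none. By Entrez identifier 21553 symbols matched the reference gene table (GRCm38.p6, used for names only), 0 changed, and 87 were kept as listed. Only probes with 1 symbol were tested, 21591 of them for 19893 genes, and for the 949 genes with several probes the one with the highest mean over the 4 arrays stood for the gene. Among probes with several symbols 1319 were tested separately in the same way, with 0 higher, 1 lower and 97 at an unadjusted p under 0.05. Among 11774 probes with no symbol the counts were 0, 0 and 713. No filter on dim probes was used and no detection call was made.

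Butyrate was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates, all 4 arrays), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are butyrate minus control. Gene lists written from general knowledge before the data were examined were tested by camera with a preset correlation of 0.01 between genes, adjusted over the 31 of 32 lists with at least 3 measured members. An estimated correlation and fry were alternatives. List members were also adjusted over the list alone. The ribosomal list follows its planned symbol rule, which takes in S6 kinases and a binding protein (68 genes); without them, a choice made after values were seen, it holds 61 genes, its adjusted p is 0.03 and 10 lists pass. That call did not hold with an estimated correlation (camera p of 0.535) or by fry (p of 0.574), nor without control replicate 1 (camera p of 0.238), and without butyrate replicate 1 the median turned to 0.04 (camera p of 0.471). Lists of MHC class I, MHC class II, Gimap and ATF4 target genes were added after values were seen.

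Named genes followed a rule fixed before the data were examined. It takes the 12 largest increases and the 12 largest decreases among genes past the threshold whose replicates did not overlap between groups, passing over predicted and unnamed genes (0 higher, 1 lower). It adds up to 4 members past the threshold of each list, or up to 2 with the largest differences where a list passed and no member did, and a fixed set of genes. Cdkn1a, Gapdh and H1f0 of that set are not analysed here, and a further gene of it is not reported here. Entpd1, Eomes, Il18r1, Ccl4 and Chac1, which complete counts of called list members, and the MHC and Gimap genes of the closing part were named after their values were seen.

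The alternatives were the replicate number as a block, restriction to the brightest 13262 or 9947 genes, quantile normalization again, subtraction of array medians, an intensity trend with a robust prior, the mean of a gene's probes, every probe, each array left out, and other thresholds. With 1 array left out the lone array is assumed to vary like the other group. Added after seeing the data were the deposited values as they stand, and the removal of values above 12. The recovery was tested on simulated ties over 34684 probes. There 250 values were solved, 0 were wrong within a tolerance of 0.001, and all 33 planted ambiguous values were left out. The simulated values were made by the same division that the recovery undoes. Whether the deposited values were made that way is therefore not tested by it. The gene test was tested on 20 simulations of the butyrate comparison with 19893 independent genes, 200 of them changed, 50 per size. It recovered 9.1% of changes of 0.7 (log2), 59.6% of changes of 1, 92.4% of changes of 1.5 and 97.9% of changes of 2. Of its calls 5.2% were false. Simulated errors were normal and independent, with variances drawn from the distribution limma had fitted. These shares describe that model and are not error rates of the calls made here. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.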

Results

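Gene expression was measured in naive CD4+ T cells from the spleens of wild-type C57BL/6 mice. The cells were cultured with interleukin-2 (IL-2) and transforming growth factor beta (TGF-beta), a combination that drives naive cells towards regulatory T (Treg) cells. Butyrate, a short-chain fatty acid that gut bacteria make and that inhibits histone deacetylases, was present in one group of cultures and absent from the other. RNA was taken at day 2. The treatment label gives 0.1 mM butyrate. Control and butyrate cultures were each represented by 2 Affymetrix whole-transcript arrays, so the number of arrays limits the precision. Nothing in the labels says whether replicates were separate cultures or animals, and p-values therefore measure only the spread between these samples, which may be technical. Log2 intensities lay between 3.72 and 14.34 on each array, with array medians of 6.70 to 6.71, and Pearson's r across probes, which are not independent replicates, was 0.986 to 0.992 between arrays. The median SD between replicates over 19893 genes was 0.106 in control and 0.10 in butyrate cultures on the log2 scale. Folds below assume that the recovered intensities are on a log2 scale, which their range and the RMA procedure imply and no source states. The values carry no detection call. Genes with a group mean under 6, a limit set after seeing the data, are therefore given without a fold, as group means or log2 differences.

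The comparison asked which genes differed in cells under Treg-inducing conditions when butyrate was present. The largest measured increase among genes past the threshold was that of H2-Ob, which encodes a chain of the H2-O protein that modulates peptide loading of MHC class II. H2-Ob rose 5.60-fold from 6.90 ± 0.10 to 9.39 ± 0.16 (log2 intensity, SD, n = 2 per group, limma adjusted p = 0.00274). The chemokine receptor Cxcr5 rose 3.76-fold, the IL-10 receptor chain Il10ra 3.36-fold, the IL-7 receptor chain Il7r 3.28-fold and the urokinase receptor Plaur 3.47-fold. Vat1 rose 4.21-fold, the stress-inducible Gadd45g 4.09-fold, the GTPase Gimap7 3.92-fold, the kinase inhibitor Camk2n1 3.42-fold and the cytokine Lif 3.37-fold. Lrrc6, a factor for assembly of ciliary dynein, rose from a dim 5.14 to 7.57 and the calcium-binding protein Rcn3 from 5.65 to 7.54 (log2 group means). With 1 array left out H2-Ob differed by 2.37 to 2.60 and Lrrc6 by 2.42 to 2.43 (log2), so their order is not settled. The largest measured decrease among the genes named was that of the inflammatory cytokine Il1a. Il1a was 7.61-fold lower with butyrate, at 7.17 ± 0.11 against 10.09 ± 0.03 (log2 intensity, SD, n = 2 per group, limma adjusted p = 0.00182). Plek, which encodes the protein kinase C substrate pleckstrin, was 6.90-fold lower. The OX40 ligand gene Tnfsf4 fell from 8.68 to 5.92, the opioid precursor gene Penk from 7.93 to 5.50 and the cystine transporter Slc7a11 from 8.14 to 5.86 (log2 group means). With 1 array left out Il1a differed by -3.00 to -2.85 and Tnfsf4 by -3.09 to -2.42 (log2), so their order is not settled. The cationic amino acid transporter Slc7a3 was 5.24-fold lower and Cth, which makes cysteine from cystathionine, 5.04-fold lower. Idi2, an isomerase of isoprenoid synthesis, was 5.96-fold lower, Spin4 5.34-fold, the glycosyltransferase Galnt3 4.78-fold, Igfbp7 4.74-fold and the activity-dependent transcription factor Npas4 4.70-fold. Adjusted p values of these 24 genes were 0.00182 to 0.0166. In total 175 genes were higher and 131 lower with butyrate at an adjusted p under 0.05 among 19893 tested, and 110 and 83 of them differed at least 2-fold in measured intensity. Tested over every probe (34684), none passed in either direction, with 3838 at an unadjusted limma p under 0.05, and on the deposited values none did. With an intensity trend and robust prior 567 were higher and 449 lower, and among the brightest 9947 genes 404 and 267. The replicates of the 2 groups did not overlap for any of these 306 genes, which a call with 2 arrays per group all but requires. Nor did they for 45.4% of all genes tested, where chance alone gives 33.3%, a difference that was not tested. Without butyrate replicate 1 the counts were 3 higher and 14 lower, without butyrate replicate 2 they were 2 and 12, and without control replicate 2 they were 281 and 112. Of the 24 genes named here, H2-Ob, Lrrc6, Il1a, Plek, Tnfsf4, Idi2, Spin4, Slc7a3, Cth, Galnt3 and Igfbp7 stayed past the threshold with each array left out, and the others had adjusted p values of 0.0506 to 0.158 without one or the other butyrate array.

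**Figure D1:**
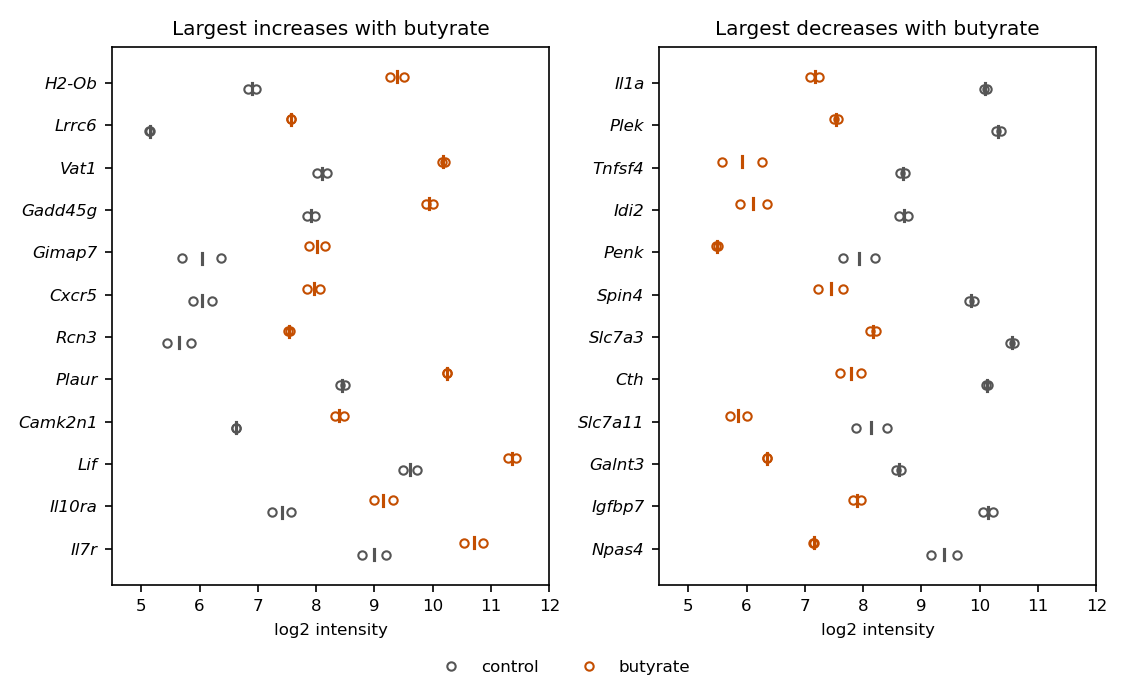
Log2 intensity (horizontal axes) of the 12 genes with the largest increases and the 12 with the largest decreases; each circle is 1 array, each short vertical line the mean of the 2 arrays of a group, control in grey and butyrate in orange. By the rule that named them, both butyrate arrays lie beyond both control arrays for each gene. H2-Ob lies at 6.90 against 9.39 and Il1a at 10.09 against 7.17 (group means).

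Among lineage regulators, Foxp3, which defines Treg cells, rose 1.93-fold with butyrate, from 11.03 ± 0.05 to 11.98 ± 0.04 (log2 intensity, SD, n = 2 per group, limma adjusted p = 0.0207). The Th1 regulator Tbx21 rose 2.98-fold (adjusted p = 0.00673) and the Th2 regulator Gata3 1.67-fold (adjusted p = 0.0415). Of 27 Treg signature genes 3 rose, Foxp3, the receptor gene Gpr83 at 2.10-fold and the ectonucleotidase Entpd1 from a dim 5.45 to 6.38 (log2), and 2 fell, Penk and the semaphorin receptor Nrp1, the latter by a factor of 1.97. The list as a whole did not pass (camera adjusted p = 0.222), and 7 members were higher and 4 lower when adjusted over the list alone. The Treg receptor genes Il2ra and Ctla4 did not pass, with log2 differences of -0.13 (95% confidence interval -0.72 to 0.46) and 0.30 (-0.01 to 0.62). With 1 array left out Ctla4 was at 0.20 to 0.41, and the sign for Il2ra turned without butyrate replicate 1 (0.26). Th1 genes went both ways. Of 17 measured, Tbx21 and the transcription factor Eomes, at 2.02-fold, were the 2 that rose. The 5 that fell were the chemokines Ccl3, 3.29-fold lower, Xcl1, 3.27-fold, and Ccl4, 2.23-fold, and the IL-18 receptor chains Il18r1, from 7.25 to 5.99, and Il18rap, from 7.04 to 5.72 (log2 group means). The median difference over the 17 was 0.04 and the mean -0.15, and the test was not passed (adjusted p = 0.707, with 7 higher and 6 lower adjusted over the list alone). That mean was -0.22 to -0.08 with 1 array left out, -0.05 without genes above 12 and -0.04 among the brightest 9947 genes. The Th17 list was lower (adjusted p = 0.000789; adjusted p = 0.453 with an estimated correlation). Of its 10 measured members 2 fell, the chemokine receptor Ccr6, 3.12-fold lower, and its ligand Ccl20, from 6.85 to 5.64 (log2 group means), and 4 were lower adjusted over the list alone. Of 11 follicular helper genes Cxcr5 rose and the membrane protein Cd200 was 1.82-fold lower, with 2 higher and 5 lower adjusted over the list alone and a list test that was not passed (adjusted p = 0.48). Of 11 Th2 genes only Gata3 passed, with 2 higher and 1 lower adjusted over the list alone and a list adjusted p of 0.329. Butyrate replicate 1 read Foxp3 just above 12, a range in which its probes had lost their order, and with such values set to missing the difference was 0.92 (adjusted p = 0.0735). The 17 genes named as changed here all lost their call, with adjusted p values of 0.0806 to 0.266, without one or the other butyrate array. Gata3 also lost its call without either control array (0.0839 and 0.0737), and Cd200, Entpd1 and Eomes without control replicate 1 (0.071, 0.073 and 0.0585).

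The list of TGF-beta response genes, which also holds receptors and ligands of TGF-beta, was higher with butyrate. Whether TGF-beta signalling itself differed was not tested. Of 18 measured, 14 had a positive difference and 2 passed, the transcriptional inhibitor Id1 at 2.00-fold and the signal transducer Smad3 at 1.88-fold, and 8 were higher adjusted over the list alone (median difference 0.33, camera adjusted p = 0.000268; adjusted p = 0.453 with an estimated correlation). Genes of naive and quiescent T cells were higher too, with a positive difference for 15 of 16. Il7r and Klf2, a transcription factor of quiescent T cells that rose 2.09-fold, passed, and 7 were higher and 1 lower adjusted over the list alone (median 0.33, adjusted p = 2.7e-05; adjusted p = 0.453 with an estimated correlation). Of 17 targets of IL-2 and STAT5, Il10ra passed, and 6 were higher adjusted over the list alone (median 0.07, mean 0.31, adjusted p = 0.0112; adjusted p = 0.453 with an estimated correlation). That call ended without butyrate replicate 2 (adjusted p = 0.0857), and 10 of the members lay above 12 on butyrate replicate 1. Without those members the mean was 0.66 over the 7 left. Early activation genes did not pass as a list (19 measured, adjusted p = 0.131). Within it the nuclear receptor Nr4a2 was 2.57-fold lower and the cytokine Il2 2.09-fold lower, and the stress response gene Ier3 rose 2.15-fold. Of its members 1 was higher and 2 were lower adjusted over the list alone. Without one or the other butyrate array the 8 genes named as changed here lost their call. With 1 array left out the log2 differences were 0.93 to 1.06 for Id1, 0.92 to 1.21 for Klf2 and -1.14 to -0.98 for Il2. Smad3 lost its call without control replicate 1 too (0.0665).

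Mitotic genes were lower with butyrate, with negative differences for 24 of 25 measured and a median of -0.33 (camera adjusted p = 2.84e-08; adjusted p = 0.453 with an estimated correlation). Only the kinetochore gene Cenpf passed alone, 1.69-fold lower (adjusted p = 0.0466), and 4 were lower adjusted over the list alone. DNA replication genes did not pass (30 measured, 15 up and 15 down in sign, none past the threshold over all genes or over the list alone, adjusted p = 0.738). In the list of the unfolded protein and integrated stress response 5 of 20 genes fell and none rose (median -0.26, adjusted p = 1.4e-06; adjusted p = 0.453 with an estimated correlation), with 1 higher and 9 lower adjusted over the list alone. The mean was -0.50, and -0.75 without the 7 members above 12 on butyrate replicate 1. The 5 were Slc7a11, which imports cystine, the asparagine synthetase gene Asns, 2.96-fold lower, the leucine sensor gene Sesn2, 2.77-fold lower, the pseudokinase gene Trib3, 2.39-fold lower, and Chac1, whose product degrades glutathione, 1.99-fold lower. Cholesterol synthesis genes were lower as a list (20 measured, median -0.14, adjusted p = 0.00764; adjusted p = 0.453 with an estimated correlation), although none passed alone and 2 were lower adjusted over the list alone. Its largest differences were -0.63 for Idi1 and -0.50 for Insig1. Both passed among the brightest 9947 genes (adjusted p = 0.0211 and 0.0374) and with an intensity trend (0.00257 and 0.0102). The fatty acid oxidation list, which also holds enzymes that activate acetate, was higher (19 measured, median 0.14, camera adjusted p = 0.0246, or 0.524 with an estimated correlation). None passed alone and 1 was higher adjusted over the list alone. Differences were 0.65 for the carnitine palmitoyltransferase Cpt1a and 0.49 for the acetate-activating Acss2. Cpt1a passed among the brightest 13262 and 9947 genes (0.0422 and 0.0167) and with an intensity trend (0.00149), and Acss2 was at 0.26 to 0.73 with 1 array left out. This call ended without control replicate 1 (adjusted p = 0.0623), without control replicate 2 (0.0619) and without butyrate replicate 1 (0.123). Glycolysis genes were lower as a list (13 measured, median -0.25, adjusted p = 0.0246; adjusted p = 0.524 with an estimated correlation), with no member past over all genes or over the list alone and a mean of -0.22. Ldha and Aldoa differed by -0.50 and -0.48, by -0.05 and -0.01 without butyrate replicate 1 and by -0.94 and -0.95 without butyrate replicate 2. The list's mean was -0.09 without the first of these and -0.35 (adjusted p = 0.000578) without the second. Of the 13, 7 lay above 12 on butyrate replicate 1. The call ended without that array and without control replicate 1 (mean -0.26). The camera adjusted p was 0.0609 among the brightest 9947 genes. It was 0.314 without those 7 members and 0.709 for the 5 members below 12 on each array. Ribosomal protein genes did not pass (68 measured, none past over all genes or over the list alone, adjusted p = 0.108), and 45 lay above 12 on butyrate replicate 1. They did pass as a list with the replicate block (camera adjusted p = 0.0344). The mean difference of the ribosomal list was -0.09, and it was -0.05 with the mean of a gene's probes, 0.04 without butyrate replicate 1, -0.23 without butyrate replicate 2 (adjusted p = 4.2e-06) and -0.10 without control replicate 2 (adjusted p = 0.01). Without one or the other butyrate array the 6 genes named as changed here lost their call. With 1 array left out the log2 differences were -0.83 to -0.69 for Cenpf, -1.67 to -1.47 for Asns and -1.07 to -0.91 for Chac1. Cenpf lost its call without either control array too (0.0822 and 0.0801), as Chac1 did without control replicate 1 (0.051).

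**Figure D2:**
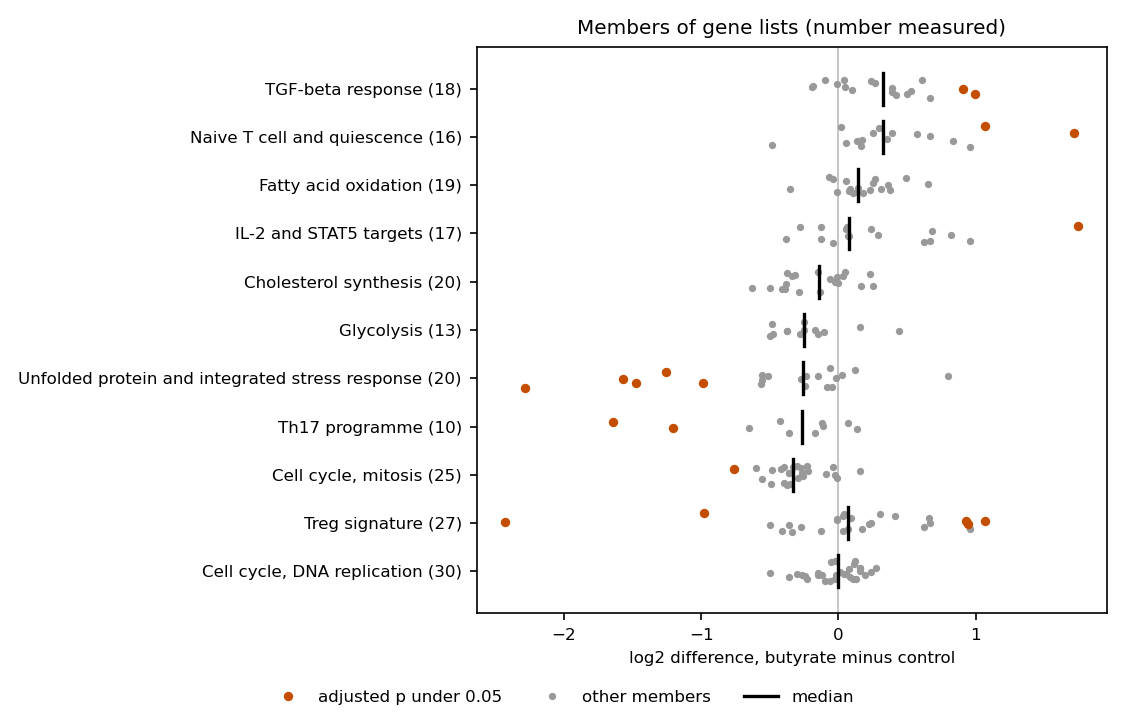
Log2 difference, butyrate minus control (horizontal axis), of each measured member of 11 gene lists, the 9 past the list test and, lowest, the Treg signature and DNA replication; orange points are genes with an adjusted p under 0.05, grey points other members and black lines list medians, and vertical position within a list carries no value. Mitotic genes lie left of 0 for 24 of 25 members and TGF-beta response genes right of 0 for 14 of 18.

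Genes that histone deacetylase inhibitors raise in other cells did not pass as a list (14 measured, camera adjusted p = 0.109). The listed H1f0 and Cdkn1a were not measured by a single-gene probe and are not among the 14. However, Gsn, which encodes the actin-severing protein gelsolin, rose 3.13-fold and the tubulin gene Tubb3 from a dim 5.25 to 5.97 (log2 group means). Adjusted over the list alone, 3 were higher and 1 lower. The deacetylases and sirtuins themselves (18 measured, adjusted p = 0.48), the acetyltransferases (12, adjusted p = 0.546) and the replication-dependent histones (11, adjusted p = 0.707) had no member past the threshold, over all genes or over the list alone. The DNA methylation machinery had none over all genes and 1 higher adjusted over the list alone (9 measured, median -0.02, mean 0.02, adjusted p = 0.927), and its maintenance genes Dnmt1 and Uhrf1 differed by -0.05 (95% confidence interval -0.42 to 0.32) and 0.04 (-0.29 to 0.37), signs that turned without butyrate replicate 1 or control replicate 2. Among butyrate receptors and transporters (9 measured, adjusted p = 0.131) the monocarboxylate transporter Slc16a7 rose from a dim 4.98 to 6.02 (log2 group means), and 2 were higher adjusted over the list alone. The receptor genes Ffar2, Ffar3 and Hcar2 did not pass, with log2 intensities of 5.10 to 5.74 in controls and differences of -0.02, whose sign turned without control replicate 1 or butyrate replicate 2, 0.37 and -0.20. Cell cycle inhibitors and p53 targets (20 measured, Cdkn1a not among them, camera adjusted p = 0.108) included the p53 target Perp, 1.97-fold lower. Adjusted over the list alone, 2 were higher and 5 lower. Of 20 interferon-stimulated genes the RNA sensor Ifih1 was 4.55-fold lower and Usp18, which removes the ubiquitin-like ISG15, rose 2.35-fold. With 7 higher and 2 lower adjusted over the list alone, the list had an adjusted p of 0.0825, which was 0.0431 without control replicate 2 and 0.0374 without butyrate replicate 2, but 0.107 without control replicate 1 (mean 0.13) and 0.151 without butyrate replicate 1. It was 0.0339 among the brightest 13262 genes and 0.0239 with the replicate block, but 0.342 among the brightest 9947 genes, where the mean was 0.06 against 0.20. Bcl-2 family and caspase genes (14 measured, adjusted p = 0.247) had none past over all genes and 3 higher and 1 lower adjusted over the list alone. Of 16 homing and chemokine receptor genes only Ccr6, 3.12-fold lower, passed, with 1 higher and 2 lower adjusted over the list alone (median 0.0025, mean -0.10, adjusted p = 0.641). With 1 array left out the mean was -0.15 to -0.04. Without one of the butyrate arrays Ifih1 kept its call, and the other genes named as changed here lost theirs. With 1 array left out the log2 differences were -2.28 to -2.09 for Ifih1, 1.34 to 1.95 for Gsn and 1.10 to 1.36 for Usp18. Tubb3 lost its call without either control array too (0.084 and 0.0838).

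T cell identity genes did not pass as a list (13 measured, median -0.20, adjusted p = 0.222), with 1 higher and 2 lower adjusted over the list alone. Of the 13, 9 lay above 12 on butyrate replicate 1. Cd4 was at 12.75 ± 0.06 in control and 12.49 ± 0.17 in butyrate cultures (log2 intensity, SD, n = 2 per group, adjusted p = 0.443), a difference of -0.37 to -0.14 with 1 array left out, and the actin gene Actb at 13.51 ± 0.01 and 13.19 ± 0.60 (adjusted p = 0.647), a difference of -0.32 that was 0.11 without butyrate replicate 1. Markers of other cell types had no member past the threshold over all genes. Median differences were -0.02 for B cells (11 measured, adjusted p = 0.742), 0.09 for myeloid and dendritic cells (18, adjusted p = 0.247), -0.03 for NK cells (8, adjusted p = 0.48) and 0.05 for erythroid cells and platelets (6, mean 0.01, camera direction down, adjusted p = 0.927). None of these lists had a member past the threshold over the list alone. With genes above 12 on any array left out, the mean difference of T cell identity genes was 0.08 over 3 members, against -0.09 over all. The CD8 T cell markers were too few for a list test, with a median difference of 0.42 over 2 genes, 1 of them higher adjusted over the list alone.

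Of 31 lists tested, 4 were higher and 5 lower with butyrate. None of the 9 calls held with an estimated correlation. Under it limma's camera passed 0 lists, with a smallest adjusted p of 0.453 and 2 lists at an unadjusted p under 0.05. That correlation was estimated from 4 arrays in 2 groups and is imprecise, so a list that fails there is not shown to be unchanged. The preset correlation is an assumption, and which of the 2 is nearer to the data was not tested. By fry, which tests whether a list's genes move on balance one way and makes no comparison with other genes, 4 of the 9 passed (IL-2 and STAT5 targets, Th17, mitosis, unfolded protein and integrated stress response), as did butyrate receptors and transporters. Bright probes had lost their order on butyrate replicate 1. Among probes above 12 on both arrays of a pair, Spearman's rho across probes was 0.25 to 0.32 between that array and the others and 0.79 to 0.83 between the others, and 694 of the genes tested were above 12 there.

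**Figure D3:**
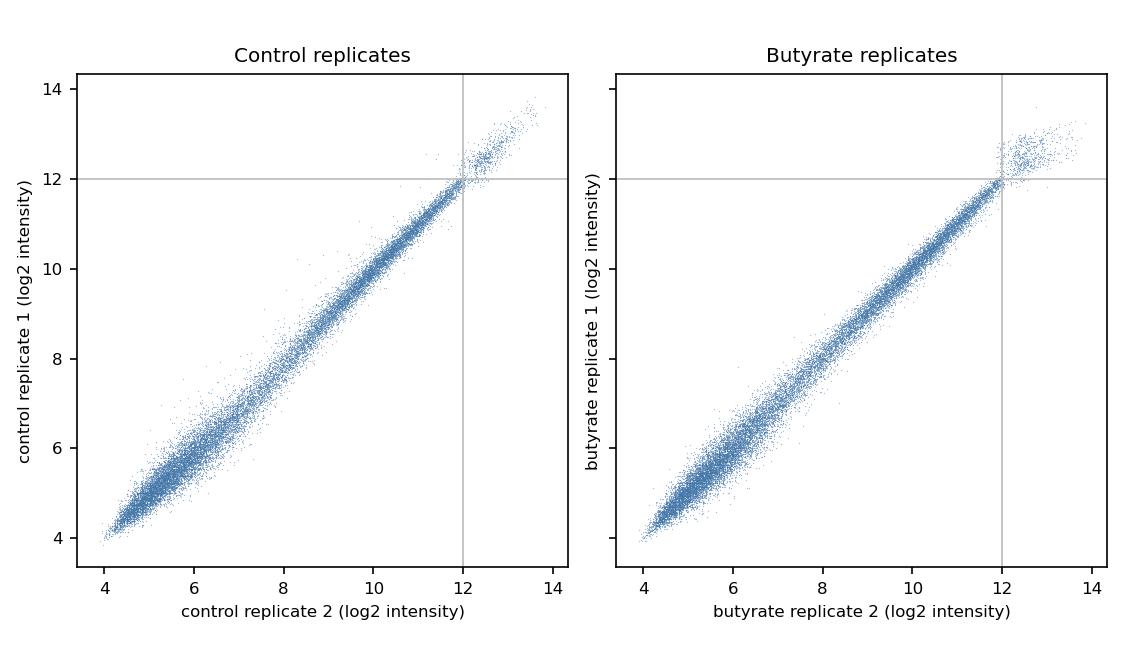
Log2 intensity of each tested gene on control replicate 1 against control replicate 2 and on butyrate replicate 1 against butyrate replicate 2, with grey lines at 12; each point is a gene. Above 12 the points of the butyrate panel spread into a cloud (Spearman's rho 0.32 across probes), whereas those of the control panel follow the diagonal (0.83).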

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

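Some alternatives were chosen after seeing the data. They set values above 12 to missing, left out genes above 12, used the deposited values as they stand or narrowed the ribosomal list. The causes of the changes given here were not tested. Among the brightest 9947 genes 404 genes were higher and 267 lower, with an intensity trend and robust prior 567 and 449, and at an adjusted p under 0.1 378 and 249. Over every probe (34684) limma called 0 higher and 0 lower, with 3838 at an unadjusted p under 0.05, and on the deposited values 0 and 0, with 1436 at an unadjusted p under 0.05 and 0 lists. Leaving out 1 array gave 2 to 281 higher and 12 to 121 lower genes, and 206 (control replicate 1), 248 (control replicate 2), 17 (butyrate replicate 1) and 14 (butyrate replicate 2) of the 306 calls remained. The other counts were 236 and 161 among the brightest 13262 genes, 176 and 134 quantile-normalized again, 183 and 135 with array medians subtracted, 173 and 131 with the mean of a gene's probes, 175 and 131 at 1.5-fold or more, 160 and 125 with values above 12 on butyrate replicate 1 missing, and 173 and 129 without genes above 12. With those values missing 285 of the 306 calls remained, and without those genes all 295 still tested did. With the replicate block 238 genes were higher, 172 lower and 11 lists passed, and 303 of the 306 calls remained; same-numbered samples deviated with a correlation of -0.036 over 2 pairs, which the labels do not tie. The block brought interferon-stimulated genes and ribosomal proteins past the threshold and changed no other call of a list or named gene. All 80 named genes also kept direction and side of the threshold when quantile-normalized again, with array medians subtracted and with the mean of a gene's probes. All 306 called genes kept their sign with each array left out, as must any gene whose replicates do not overlap between groups. The calls lost there were therefore not changes of direction. An estimated correlation left 0 lists and fry 5.

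Mean log2 differences of lists that turned sign were as follows. For list means, setting values above 12 to missing dropped each gene above 12 on butyrate replicate 1 whole. It therefore nearly repeats leaving out genes above 12 on any array. Both settings put the Treg signature at -0.013, DNA replication at 0.010, DNA methylation at -0.030 and ribosomal proteins at 0.0032. Without genes above 12 the Tfh list was at 0.099 and T cell identity at 0.085. Among the brightest 13262 genes the Tfh list was at 0.0039 and erythroid and platelet markers at -0.019, and with array medians subtracted the Tfh list was at 0.0024. With 1 array left out the means ranged from -0.021 to 0.018 (Tfh), -0.037 to 0.0037 (histones), -0.041 to 0.087 (DNA methylation), -0.10 to 0.12 (erythroid and platelet) and -0.23 to 0.040 (ribosomal, past the threshold at -0.23, without butyrate replicate 2). Among genes, the values with those above 12 missing were 0.26 for Il2ra, 0.030 for Dnmt1 and 0.11 for Actb. Ranges with 1 array left out were -0.51 to 0.26 for Il2ra, -0.21 to 0.11 for Dnmt1, -0.083 to 0.16 for Uhrf1, -0.15 to 0.10 for Ffar2 and -0.74 to 0.11 for Actb. Signal near the array floor, as for the butyrate receptor genes and others with a group mean under 6, limits what differences can be seen there.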

Other observations

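The lists of MHC class I, MHC class II, Gimap and ATF4 target genes were drawn up after values had been seen, and so were the tests of the lost order, of the division by ties, of a ceiling and of other cell types chosen; the brightness and ATF4 tests were written down before their results. Gimap genes, which encode GTPases of lymphocyte survival, had a positive difference for 7 of 8 (median 0.70). Gimap7 rose 3.92-fold, Gimap4 1.79-fold and Gimap3 1.72-fold (limma adjusted p = 0.0166, 0.0487 and 0.038). Gimap7 prompted that list, so no list test and no adjustment over the list alone is given. Without one or the other butyrate array the adjusted p of these 3 genes was 0.129 to 0.274. Gimap4 also lost its call without control replicate 1 (log2 difference 0.70), and Gimap3 without either control (0.81 and 0.75). With values above 12 on butyrate replicate 1 missing, Gimap4 had a limma adjusted p of 0.0515. Its difference was then 0.84, as in the main test. Of 10 genes of MHC class I presentation Nlrc5, its transcriptional activator, rose 2.06-fold and the immunoproteasome subunit Psmb8 1.74-fold. However, 5 differences were positive and 5 negative (median 0.04, camera p of 0.236), with 3 higher and 1 lower adjusted over the list alone. That median was -0.02 without control replicate 1, 0.10 without control replicate 2 and 0.17 over the 8 members left without genes above 12. Nlrc5 and Psmb8 lost their call without control replicate 1 and without one or the other butyrate array. Their log2 differences were 0.92 to 1.16 and 0.73 to 0.86 with 1 array left out. Splitting the 4 arrays the other ways gave 0 genes at most, against 306 for the labels' split. Each other split sets 1 control with 1 butyrate array in both groups, so the butyrate difference widens its spread and lowers its count. These counts are therefore no measure of false calls, and 3 splits are too few for a share under 0.05.

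In the list of the unfolded protein and integrated stress response Slc7a11, Asns, Sesn2, Trib3 and Chac1 fell, the other 15 of 20 members did not pass, and the list was lower (adjusted p = 1.4e-06; adjusted p = 0.453 with an estimated correlation). The lost order of bright probes on butyrate replicate 1 does not account for it, since that list's median was -0.255 without that array. Nor does a trend with brightness. Also without that array, 10000 random lists of matched intensity had a typical median of -0.022, and 0.02% of them lay as low as the list. Genes of a random list need not move together as list members may, so that share is no p-value for the list. All 23 ATF4 targets whose values had not been looked at were negative (median -0.29, camera p of 1.24e-08, or 0.0243 with an estimated correlation; 7.68e-07 without butyrate replicate 1). That list was made because ATF4 targets had fallen, and it was visible that none of its members was called. Lower activity of ATF4, the transcription factor of the integrated stress response, may be a candidate explanation. Whether butyrate acts on it or on amino acid supply was not tested.

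Bright probes lost their order on butyrate replicate 1. An error in undoing the division by ties does not account for it, since bright probes with untied values, which the recovery leaves as they are, had a Spearman's rho of at most 0.323 across probes with another array. On both butyrate arrays 1299 probes lay above 12, against 1296 on both control arrays, so the same probes stayed bright while their order was lost. A ceiling on that array may be the cause, an explanation found from these values. No biological explanation was tested.

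Of 8 measured MHC class II genes all were higher in mean (median 0.67). H2-Ob, H2-Ab1 (5.91 to 7.38, log2 group means) and H2-Oa (2.40-fold) passed over all genes. No list test and no adjustment over the list alone is given, since H2-Ob prompted the list. Differences of marker genes had a median plus 1 SD of 0.108 for B cells and 0.307 for myeloid or dendritic cells (butyrate minus control). Both lay below the class II median of 0.67, but 9 of 11 and 12 of 18 markers were under 6 in controls, near the floor. Neither cell type in the butyrate samples is therefore excluded as an explanation. H2-Aa, H2-Eb1 and Cd74 differed by 0.35, 0.26 and 0.61 and did not pass. H2-Aa lay near the floor, at 4.93 in control and 5.28 in butyrate cultures (log2 group means). Cd74 passed among the brightest 9947 genes (limma adjusted p = 0.0247) and with an intensity trend (0.00278). With 1 array left out H2-Aa was at 0.02 to 0.68 and H2-Eb1 at 0.01 to 0.51. Without one or the other butyrate array H2-Ob kept its call, and H2-Ab1 and H2-Oa had adjusted p values of 0.0848 to 0.22. Expression by the T cells themselves, which was not tested, may be a candidate explanation beside cells of another type, although the labels describe the cells as naive CD4+ T cells.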
